A study of Skeletonema marinoi with 15 samples.

How the data were processed

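Messenger RNA levels were measured by sequencing of 15 libraries of Skeletonema marinoi, a chain-forming marine diatom, from a culture whose label names Jiaozhou Bay. Libraries were placed in 6 groups by the treatment or growth phase in their labels. The exponential phase, named as the control, had 2 libraries, numbered 1 and 3. The declining phase, the stationary phase, low temperature and low silicate had 3 libraries each, and high temperature had 1. The study's design text calls the replicates biological. The order of the declining and stationary phases in time, the temperatures and the silicate levels are not given in the sources used here.

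Per the file headers, each library's deposited table holds a read count and an FPKM value for each assembled feature. The deposited counts are expected counts (estimates that need not be whole): 15.8% to 24.4% of the values in a library were not whole, at a tolerance of 1e-06, so each was rounded to a whole number before any count test. FPKM is the deposited count per kilobase of feature, scaled to a common library total, and the length implied by count and FPKM was nearly constant over the libraries, with a median coefficient of variation of 0.104%. Per the submitters' processing notes, Bowtie 0.12.2 was used and the build mm8 was named. That build is a mouse genome and cannot be the reference of a diatom table, and the feature IDs have the form that de novo transcript assemblers write. The counter, the assembly, the annotation and any filter are not given in the sources used here. No strand setting is given, and reads split between near-identical assembled features could not be traced, so each feature's level carries that uncertainty.

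The files do not pair feature IDs with gene names, and no annotation of this diatom was used here. The gene lists fixed before the data were examined, which included markers of bacteria, organelle transcripts and ribosomal RNA, were keyword lists on gene names and could therefore not be tested. Features are named by the IDs in the files. The rule for naming them, fixed beforehand, took for each comparison the 2 largest rises and the 2 largest falls among features past the threshold. Such a feature needed a mean of at least 10 CPM (counts scaled to a common library total) over all libraries and no overlap between the values of the 2 groups compared. For the high temperature comparison, non-overlap means that its library lay outside the range of the control libraries.

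Each table held 20319 features, of which 123 had no read in any library. The filter of edgeR (filterByExpr, on the groups) kept 14652 features and left out 5667, which held 0.024% to 0.115% of the reads of a library. Library totals ran from 7595273 to 13032623 reads. Replicate libraries were compared before they were averaged: over features with at least 10 reads in a pair, chi-square per degree of freedom was between 13.4 and 309.7, so no pair agreed within sampling noise. Counts were scaled with trimmed mean of M values (TMM) factors, which ran from 0.599 in stationary 2 to 1.57 in exponential 3. All 15 libraries entered a single fit with 1 mean per group. The common dispersion was 0.187, a biological coefficient of variation of 43.3%.

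The 7 comparisons were tested with edgeR 4.0.16 in R 4.3.3, by its quasi-likelihood F test with Benjamini-Hochberg adjustment over the features tested, and a feature was called at an adjusted p under 0.05. Standard errors (SE) are the absolute log2 fold change over the square root of F. The single high temperature library was assumed to vary like the libraries of the other groups, and a difference that involves it has no replicate check of its own. CPM values are TMM-scaled and given as mean ± SD over libraries. A group with no read for a feature was given a floor of 3 reads over its libraries, and folds against it are lower bounds. Folds against 1 to 3 reads are ratios of pooled reads with exact Clopper-Pearson 95% intervals. Intervals and floors cover counting error only, since duplicate reads cannot be told from separate molecules.

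Abundance classes were formed by mean CPM over all libraries: the 100 most abundant features, those next in rank down to rank 1000, and the rest. They were tested against the other features with camera in limma 3.58.1 on voom values at a preset correlation of 0.01, and again with an estimated correlation, adjusted over all classes and comparisons. The estimate is made within the class tested: 0.004 for the rest and 0.323 to 0.506 for the other 2, ranked on all libraries. Features outside the class are taken as independent, so the test of the rest does not allow for the correlation within those 2 classes. Quartiles of implied length were tested in the same way, and a length was had for 12850 of the tested features (87.7%), with a median of 1302 bases. Detected features were counted after each library was thinned at random to 7595273 reads. Overlaps between comparisons that share the control libraries were set beside the overlap of independent lists, beside 20 simulated sets of unchanged groups and beside fits in which each comparison had its own control library.

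The test was first run on simulated counts drawn from the libraries' own means, dispersions and totals, with 200 features changed per comparison. For declining against exponential, over 14410 features, 0% of the 2-fold, 7.5% of the 4-fold and 36.4% of the 8-fold changes were recovered. For low silicate against exponential, over 14430 features, these shares were 1.5%, 10.4% and 56.1%. For high temperature against exponential, over 14401 features, they were 0%, 3.0% and 16.7%. At most 5 unchanged features were called in any of the 7 simulations. Changes of 2-fold were therefore mostly not recovered in these simulations. With only 200 features changed, the adjustment is stricter than in fits with many calls, so recovery there may be higher. For declining against exponential, 3730 features were called in the real fit, of which 3656 changed at least 2-fold.

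Alternatives fixed beforehand were RLE scaling in the same test, the Wald test of DESeq2 1.42.0, limma-trend on log2(FPKM + 1) and on log2(FPKM + 0.1), no filter on low counts, only the 2 groups compared, a replicate block, a minimum absolute log2 fold change of 1 and leaving out each replicate in turn. Chosen after seeing the data were scaling by library totals alone, ranking the abundance classes on the low silicate libraries, leaving out features read mostly in exponential 1, and leaving out the libraries exponential 1 and stationary 3. The simulated and separate-control values for features that moved alike in 3 comparisons were also chosen then.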

Results

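Transcript levels of S. marinoi were read as counts per assembled feature in 15 libraries. Growth of a batch culture was represented by the exponential phase (the control, n = 2), the declining phase (n = 3) and the stationary phase (n = 3). Low temperature (n = 3), high temperature (n = 1) and low silicate (n = 3) were set against the same control. Diatoms build their cell walls from silica, so silicate is a nutrient for them. Read totals were 7595273, 11625387 and 9596510 for declining 1 to 3, and 10749097 and 9887315 for exponential 1 and 3. Stationary 1 to 3 held 9606364, 11180383 and 8593498 reads, and high temperature 10337341. Low temperature 1 to 3 held 12603833, 13032623 and 9928270 reads, and low silicate 1 to 3 held 9011336, 11105080 and 9915388. The files do not pair the feature IDs with gene names, so features are given by ID and by groups of features.

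Exponential libraries drew on the largest number of features of the 6 groups. At an equal depth of 7595273 reads, 17285 ± 205 features had a read in the exponential phase (SD, n = 2), 16650 ± 136 under low silicate (n = 3) and 15380 ± 618 under low temperature (n = 3). The number was 15313 ± 363 in the declining phase (n = 3) and 14181 ± 290 in the stationary phase (n = 3), and 15858 in the high temperature library. The 100 most abundant features of each library took 26.9% ± 2.65 of the reads in the exponential phase, 34.6% ± 1.5 in the declining phase and 36.6% ± 2.32 in the stationary phase. They took 31.5% ± 1.05 under low temperature, 30.1% ± 1.08 under low silicate and 27.7% in the high temperature library. The declining, stationary, low temperature and low silicate libraries all lay above both exponential libraries in this share and below both in detected features. The separation is therefore not particular to the late phases, and no test was run on either measure. The smallest one-sided exact p of 3 libraries against 2 is 0.1. The stationary share was 1.36 times the exponential share, and 1.19 times with 1000 in place of 100 features.

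Declining and stationary libraries were on average more alike than the 2 exponential libraries. The mean correlation across features of log2 CPM was 0.976 within the declining phase, 0.948 within the stationary phase, 0.945 within low silicate, 0.944 within low temperature and 0.921 between the exponential libraries. Between groups it was 0.942 for declining and stationary, 0.907 for exponential and low silicate, 0.83 for exponential and declining, and 0.828 for exponential and low temperature. These correlations are over features, which are not independent replicates. On the first 2 principal components, with 35.5% and 23.6% of the variance, the exponential and low silicate libraries lay at one end of the first. Stationary 3 lay apart from its group on the second, at 8.7, with stationary 1 at -65.3 and stationary 2 at -51.0, and the low temperature libraries lay between 65.8 and 120.6. The exponential libraries lay within that range, at 70.5 and 71.4, and low silicate between -22.1 and 6.4, so this component is not specific to low temperature.

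**Figure D1:**
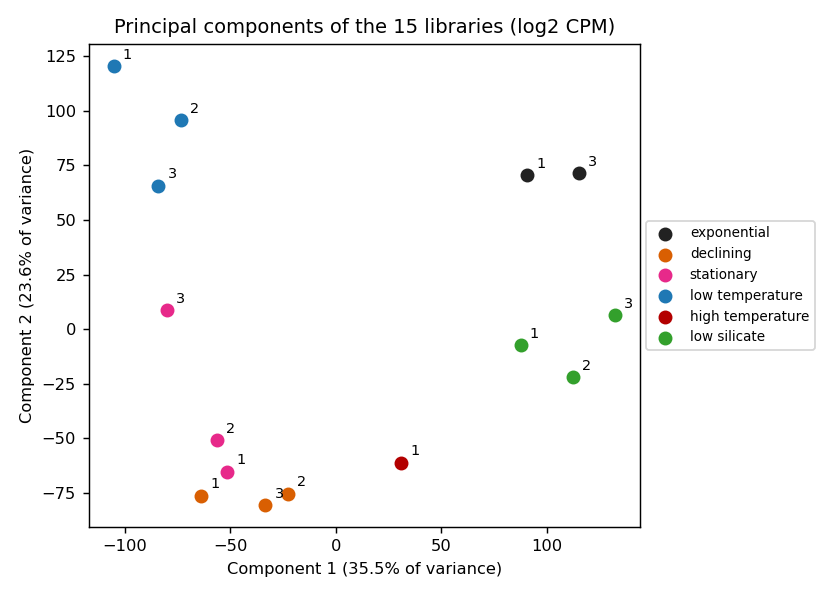
Principal components of log2 CPM of the 15 libraries, with component 1 (35.5% of the variance) on the horizontal and component 2 (23.6%) on the vertical axis, both in log2 units. Each point is a library, its colour gives the group and its number the replicate. Stationary 3 sits at 8.7 on component 2, between the other stationary libraries and the low temperature libraries. The exponential libraries, at 70.5 and 71.4, lie within the range of the low temperature libraries there.

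In the declining phase, transcripts of 1655 features rose and those of 2075 fell relative to the exponential phase, 25.5% of the 14652 features tested. Features that rose held 7.95% ± 0.96 of the reads in the exponential phase and 26.3% ± 1.46 in the declining phase, and those that fell went from 13.4% ± 2.44 to 2.06% ± 0.23 (SD, n = 2 and 3). Their median log2 fold changes were 2.42 and -3.33, or 2.41 and -2.98 with features unread in 1 group set to their bound. Of those that fell, 309 had no read in any declining library. The largest rises by the naming rule were comp10281_c0, from 0.129 ± 0.182 to 148 ± 21.5 CPM (log2 fold change 9.95, SE 1.37, edgeR adjusted p = 0.00042), and comp21032_c0, from 0.25 ± 0.081 to 104 ± 80.5 CPM (8.65, SE 1.01, edgeR adjusted p = 0.000201). The largest falls were comp11834_c0, from 464 ± 324 to 1.13 ± 1.18 CPM (-8.66, SE 1.42, edgeR adjusted p = 0.00109), and comp19209_c0, from 62.8 ± 5.51 to 0.251 ± 0.109 CPM (-7.88, SE 1.07, edgeR adjusted p = 0.000397). The naming rule required that the 2 groups not overlap for each of these 4. Over all features tested, the groups did not overlap for 60.9%, where chance gives 20%.

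Abundance classes were ranked on all 15 libraries, so a feature that rises in a group is more easily placed in a high class, and classes ranked on the low silicate libraries are given beside them. Of the 100 most abundant features, 18 rose and 3 fell, with a median log2 fold change of 1.06 (camera adjusted p = 4.99e-07), and adjusted p = 0.596 with an estimated correlation. Of the features next in rank, down to rank 1000, 166 rose and 40 fell, with a median of 0.58 (camera adjusted p = 8.54e-07), and adjusted p = 0.611 with an estimated correlation. The rest had a median of -0.07, with 1471 that rose and 2032 that fell (camera adjusted p = 1.89e-07, and 0.00024 with an estimated correlation). Here and in later comparisons, that last value mirrors the test of the first 2 classes without their correlation, and is not separate support for a fall. Ranked on the low silicate libraries, the first 2 classes had medians of 0.85 (camera adjusted p = 0.000159, and 0.799 with an estimated correlation) and 0.38 (camera adjusted p = 0.0097, and 0.913 with an estimated correlation). With library totals alone as the scaling, the median over all features moved to -0.58, 888 features rose and 3413 fell, and the class medians were 0.51 for the 100 most abundant and 0.03 for those next in rank. The test on log2(FPKM + 1) gave 991 and 3450. Calls numbered 2056 without exponential 3 (498 that rose and 1558 that fell), 2412 without exponential 1 (859 and 1553) and 2240 without declining 1 (999 and 1241).

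In the stationary phase, 1778 features rose and 2228 fell relative to the exponential phase, 27.3% of those tested. Features that rose went from 23.0% ± 4.85 to 48.2% ± 4.82 of the reads, and those that fell from 9.89% ± 3.49 to 1.09% ± 0.11 (SD, n = 2 and 3). Median log2 fold changes were 2.08 and -2.89, or 2.07 and -2.69 with unread features at their bound, and 254 of those that fell had no read in any stationary library. By the naming rule, comp16328_c0 rose from 2.11 ± 1.70 to 378 ± 152 CPM (7.49, SE 1.12, edgeR adjusted p = 0.001), and comp17831_c0 from 0.611 ± 0.319 to 105 ± 73.1 CPM (7.37, SE 1.55, edgeR adjusted p = 0.00493). The falls were comp12963_c0, from 34.7 ± 38.9 CPM to no read in 3 libraries (at least 226-fold lower, edgeR adjusted p = 0.000833), and comp11834_c0, from 464 ± 324 to 0.72 ± 0.765 CPM (-9.38, SE 1.5, edgeR adjusted p = 0.00126). The 2 exponential libraries differed widely in comp12963_c0, at 94 and 967 reads. The groups did not overlap for 53.3% of the features, where chance gives 20%.

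Among the 100 most abundant features 53 rose and 1 fell in the stationary phase, with a median log2 fold change of 1.81 (camera adjusted p = 4.61e-17), and adjusted p = 0.393 with an estimated correlation. Among those next in rank, down to rank 1000, 370 rose and 14 fell, with a median of 1.26 (camera adjusted p = 3.02e-24), and adjusted p = 0.393 with an estimated correlation. The rest had a median of -0.20, with 1355 that rose and 2213 that fell (camera adjusted p = 7.89e-26, and 2.33e-06 with an estimated correlation). Ranked on the low silicate libraries, the first 2 classes had medians of 1.51 (camera adjusted p = 1.14e-12, and 0.496 with an estimated correlation) and 0.99 (camera adjusted p = 5.99e-14, and 0.463 with an estimated correlation). With library totals alone, the median over all features moved to -1.16, 570 features rose and 5835 fell, and the first 2 classes had medians of 0.79 and 0.23. The test on log2(FPKM + 1) gave 549 and 5802. Of the quartiles of feature length, the longest passed in this comparison (median 0.21, camera adjusted p = 0.0454), with adjusted p = 0.35 with an estimated correlation, and no length quartile passed the preset test in the other 6 comparisons. Calls numbered 1249 without exponential 3 (268 that rose and 981 that fell), where comp17831_c0 no longer passed (edgeR adjusted p = 0.053), and 2550 without stationary 2 (1144 and 1406).

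Set directly against each other, the stationary and declining phases differed in 22 features, 13 higher and 9 lower in the stationary phase, and 2795 had an unadjusted p under 0.05. By the naming rule, comp12537_c1 was higher in the stationary phase (34.1 ± 32.7 against 0.61 ± 0.341 CPM, log2 fold change 5.76, SE 0.93, edgeR adjusted p = 0.0423), as was comp20124_c0 (35.9 ± 35.0 against 1.35 ± 0.729 CPM, 4.73, SE 0.79, edgeR adjusted p = 0.0423). Lower were comp19556_c0 (8.01 ± 2.97 against 70.0 ± 17.3 CPM, -3.13, SE 0.56, edgeR adjusted p = 0.0472) and comp19760_c0 (69.4 ± 20.6 against 317 ± 39.7 CPM, -2.19, SE 0.3, edgeR adjusted p = 0.0423). The 100 most abundant features had a median log2 fold change of 0.58 with no member called (camera adjusted p = 8.45e-10, and 0.502 with an estimated correlation), or 0.09 with library totals alone, where the median over all features was -0.55. The features next in rank, down to rank 1000, had a median of 0.55 with 1 higher and 0 lower (camera adjusted p = 2.58e-19, and 0.393 with an estimated correlation), or 0.06 with library totals alone. The rest had a median of -0.12, with 12 higher and 9 lower (camera adjusted p = 8.26e-20, and 4.05e-06 with an estimated correlation). Ranked on the low silicate libraries, the first 2 medians were 0.57 and 0.53 (camera adjusted p = 2.6e-09 and 8.81e-18, and 0.594 and 0.389 with an estimated correlation). The groups did not overlap for 30% of the features, where chance gives 10%. The count was 0 with edgeR when any of declining 1, declining 2, declining 3, stationary 2 or stationary 3 was left out, and 261 without stationary 1, while DESeq2 called 1016 with all libraries (713 higher, 303 lower). The split was 41 higher and 15 lower with RLE scaling, 16 and 32 with library totals alone and 27 and 121 on log2(FPKM + 1).

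Under low temperature, 1989 features rose and 2050 fell relative to the exponential phase, 27.6% of those tested. Features that rose went from 9.07% ± 0.2 to 31.5% ± 9.16 of the reads, and those that fell from 9.98% ± 2.98 to 1.67% ± 0.25 (SD, n = 2 and 3). Median log2 fold changes were 2.60 and -2.43, or 2.57 and -2.39 with unread features at their bound. At least 16-fold rises numbered 451 and falls 307, counted with those bounds. The feature comp10738_c0 had 1 read in the exponential libraries and 514 ± 252 CPM under low temperature, a ratio of 13198 (95% interval 2368 to 521331.5, edgeR adjusted p = 0.000161). The feature comp15044_c0 had 2 reads there and 62.3 ± 54.1 CPM under low temperature, a ratio of 1018 (282 to 8414, edgeR adjusted p = 0.00045). Falls were led by comp17274_c0, from 21.1 ± 6.05 CPM to 1 read in 3 libraries (ratio 713, 127.5 to 28205, edgeR adjusted p = 3.66e-05), and comp5445_c0, from 237 ± 115 to 1.07 ± 0.518 CPM (log2 fold change -7.84, SE 0.67, edgeR adjusted p = 4.57e-05). Non-overlap held for 52.6% of the features, where chance gives 20%.

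Of the 100 most abundant features, 16 rose and 1 fell under low temperature, with a median log2 fold change of 0.77 (camera adjusted p = 0.000327), and adjusted p = 0.669 with an estimated correlation. Those next in rank, down to rank 1000, had 155 that rose and 29 that fell and a median of 0.54, which became -0.11 with library totals alone (camera adjusted p = 8.3e-06, and 0.631 with an estimated correlation). The rest had a median of -0.18, with 1818 that rose and 2020 that fell (camera adjusted p = 4.46e-06, and 0.000503 with an estimated correlation). No class passed when ranked on the low silicate libraries: medians were 0.35 (camera adjusted p = 0.515) and 0.27 (camera adjusted p = 0.232) for the first 2. With library totals alone, the median over all features moved to -0.71, that of the 100 most abundant to 0.14, and 1175 features rose and 3938 fell. The test on log2(FPKM + 1) gave 1256 and 4159. Other settings turned the balance to rises: 1653 rose and 1270 fell without low temperature 1, and 1742 and 1289 without low temperature 2. Without low temperature 3 these numbers were 1905 and 1778, and in a fit of these groups alone 1417 and 1286. Calls numbered 2098 without exponential 3 (736 that rose and 1362 that fell) and 2567 without exponential 1 (1115 and 1452).

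In the single high temperature library, 553 features were higher and 378 lower than in the exponential phase, 6.4% of those tested, under the assumption that it varies like libraries of the other groups. Features that were higher held 9.68% of its reads and 1.29% ± 0.2 in the exponential phase, and lower ones 0.37% and 4.43% ± 0.17 (SD, n = 2). By the naming rule, comp21032_c0 stood at 754 CPM against 0.25 ± 0.081 (log2 fold change 11.51, SE 1.14, edgeR adjusted p = 0.000649), and comp16328_c0 at 3973 CPM against 2.11 ± 1.70 (10.89, SE 1.32, edgeR adjusted p = 0.00166). Lower were comp6462_c0, with no read against 10.3 ± 4.03 CPM (at least 43.5-fold lower, edgeR adjusted p = 0.0275), and comp16723_c0, with 1 read against 55.2 ± 22.9 CPM (ratio 679.6, 95% interval 122 to 26859, edgeR adjusted p = 0.00244). No abundance class passed camera here. The library lay outside the range of the exponential libraries for 77.4% of the features, where chance gives 66.7%. The balance of calls turned with the scaling and with other choices: 385 were higher and 415 lower with RLE scaling, 256 and 356 with library totals alone, 719 and 1085 with DESeq2, 542 and 1241 on log2(FPKM + 1), and 391 and 572 in a fit of these groups alone. Calls numbered 55 without exponential 3 (24 higher and 31 lower), 103 without exponential 1 (67 and 36), and 199 without exponential 1 and stationary 3 (109 and 90). The call of comp6462_c0 ended in each of these 3 fits (edgeR adjusted p = 0.0681, 0.0758 and 0.0508).

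Between low and high temperature, 789 features were higher and 1138 lower under low temperature, 13.2% of those tested. The rises comp22349_c0 (80.7 ± 47.0 CPM, at least 340.3-fold higher, edgeR adjusted p = 0.035) and comp12295_c0 (69.4 ± 44.8 CPM, at least 292.5-fold higher, edgeR adjusted p = 0.00745) had no read in the high temperature library. The feature comp12137_c0 had no read in 3 low temperature libraries and 39.2 CPM in the high temperature library (at least 433-fold lower, edgeR adjusted p = 1.75e-05). The feature comp10863_c0 had 3 reads against 180 CPM, where the ratio was 1985 (95% interval 678 to 9631, edgeR adjusted p = 0.00119). The 100 most abundant features had 8 that were higher and 1 that was lower, with a median log2 fold change of 0.47 that became -0.03 with library totals alone (camera adjusted p = 0.0294, and 0.767 with an estimated correlation). Those next in rank had 79 higher and 42 lower and a median of 0.58, or 0.08 with library totals alone (camera adjusted p = 0.000279, and 0.669 with an estimated correlation). The rest had a median of 0, with 702 higher and 1095 lower (camera adjusted p = 0.000274, and 0.00188 with an estimated correlation). Ranked on the low silicate libraries, no class passed, with medians of 0.12 (camera adjusted p = 0.853), 0.32 (camera adjusted p = 0.195) and 0 (camera adjusted p = 0.223). With library totals alone, the median over all features was -0.33, and 523 features were higher and 1699 lower. DESeq2 turned the balance, with 1776 higher and 1286 lower. Calls numbered 1059 without low temperature 2 and 310 in a fit of these groups alone. The call of comp22349_c0 ended without low temperature 1 (edgeR adjusted p = 0.0532) and without low temperature 2 (edgeR adjusted p = 0.054).

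Under low silicate, 16 features rose and 59 fell relative to the exponential phase, 0.5% of those tested, and 2336 had an unadjusted p under 0.05. The features that fell went from 1.24% to 0.19% ± 0.07 of the reads, and those that rose from 0.02% to 0.11%. By the naming rule, comp21032_c0 rose from 0.25 ± 0.081 to 12.8 ± 9.39 CPM (log2 fold change 5.63, SE 0.92, edgeR adjusted p = 0.0159), and comp13781_c0 from 1.80 ± 2.00 to 85.1 ± 58.5 CPM (5.54, SE 0.97, edgeR adjusted p = 0.0267). The feature comp11818_c0 fell from 39.9 ± 2.62 to 0.522 ± 0.497 CPM (-6.30, SE 0.7, edgeR adjusted p = 0.00231), and comp10390_c0 from 72.0 ± 12.7 to 2.51 ± 2.18 CPM (-4.86, SE 0.93, edgeR adjusted p = 0.0347). No abundance class passed camera in this comparison. The groups did not overlap for 33.7% of the features, where chance gives 20%. The count rested on single libraries: 6 without exponential 1, 19 without low silicate 2, 195 without low silicate 1 and 192 without low silicate 3. The calls of comp21032_c0, comp13781_c0 and comp10390_c0 ended without exponential 1 (edgeR adjusted p = 0.162, 0.164 and 0.162), those of the first and last without exponential 3 (0.09 and 0.0596), those of the last 2 without low silicate 2 (0.0801 and 0.157), and that of the last without low silicate 3 (0.064). A fit of these groups alone called 0 with edgeR, and DESeq2 called 553 with all libraries.

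**Figure D2:**
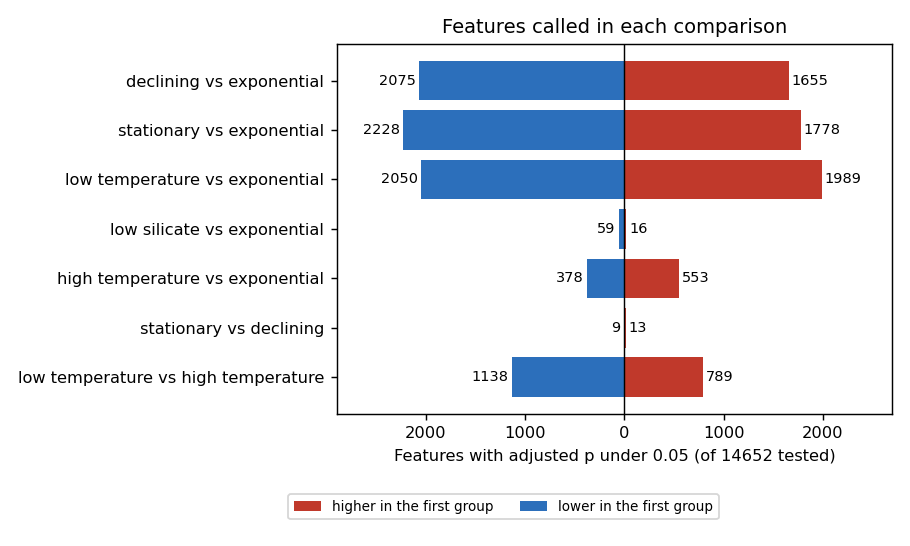
Number of features called in each of the 7 comparisons (edgeR, adjusted p under 0.05, of 14652 tested), with those higher in the first group to the right of 0 and those lower to the left. The declining, stationary and low temperature groups each differed from the exponential phase in over 1000 features per direction, and low silicate in 16 and 59.

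The declining and stationary phases shared 1050 features that rose and 1449 that fell, and none was called in opposite directions. Independent lists of these lengths would share 200.8 and 315.5. Low temperature and the stationary phase shared 903 that rose and 1162 that fell (241.4 and 311.7 for independent lists), with 31 in opposite directions, 2 that rose and 29 that fell under low temperature (302.4 and 248.8). That overlap was not counted without stationary 3, which lay apart from the other stationary libraries, so how far it rests on that library is not known. Low and high temperature shared 234 that rose and 199 that fell (75.1 and 52.9 for independent lists), with 47 in opposite directions, 1 that rose and 46 that fell under low temperature, fewer than the 51.3 and 77.4 of independent lists. Unchanged groups simulated against the same control libraries gave mean correlations over 20 draws of log2 fold changes across features of 0.58, 0.58 and 0.41 for these 3 pairs, where 0.84, 0.76 and 0.51 were observed, and 0.65 or 0.54, 0.45 or 0.54, and 0.30 or 0.20 with a control library of its own for each. Covariances were 4.43, 3.80 and 2.55, and 0.39, 0.39 and 0.38 in the simulations, differences of 4.04, 3.41 and 2.18. With such separate controls, the shared calls in the same direction numbered 885 or 991, 716 or 661, and 47 or 17. In the simulated unchanged groups, 0 calls were shared in the same direction in any draw for these 3 pairs. Part of the excess may still come from the shared control libraries. The split fits cannot show how much, since a single control library on either side lowers the number of calls in any case.

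Of 50 features called in both, 37 rose under low temperature and fell under low silicate, 6 did the opposite, and 2 rose and 5 fell in both. Independent lists would give 8.0, 2.2, 2.2 and 8.3. These counts rest on the 75 low silicate calls, which numbered 6 without exponential 1, 19 without low silicate 2 and 0 with edgeR in the fit of 2 groups (2336 had an unadjusted p under 0.05 with all groups, and DESeq2 called 553). Against the stationary phase, 26 features that fell under low silicate rose, and 14 of the 16 that rose under low silicate rose there too, where independent lists would give 7.2 and 1.9, while 8 fell in both and 1 rose under low silicate and fell there (9.0 and 2.4). Against the declining phase these numbers were 23 and 14 (6.7 and 1.8), and 10 and 1 (8.4 and 2.3). Correlations of log2 fold changes with low silicate were 0.48 for stationary and 0.61 for declining, 0.59 and 0.60 in the simulations, and 0.03 or 0.17 and 0.21 or 0.24 with separate controls. The covariances went the other way, at 1.43 for stationary and 1.84 for declining, and 0.39 for each in the simulations. The feature comp10390_c0 was among those that moved apart, with a log2 fold change of 3.23 under low temperature (edgeR adjusted p = 0.0248) and -4.86 under low silicate (edgeR adjusted p = 0.0347). The feature comp13781_c0, which rose under low silicate, fell in the declining phase (-3.55, edgeR adjusted p = 0.0293) and the stationary phase (-4.87, edgeR adjusted p = 0.0204). Both falls are near the floor and rest mostly on exponential 3, with 50 reads, where exponential 1 had 5. Its reads were 1, 2 and 1 in declining 1 to 3 and 0, 1 and 0 in stationary 1 to 3. The correlation of log2 fold changes across features between low temperature and low silicate was 0.30, and 0.61 in the simulations, and it was -0.06 and -0.08 with a control library of its own for each. The covariance was 0.88, and 0.39 in the simulations.

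A set of 710 features rose in the declining phase, the stationary phase and under low temperature alike, and 853 fell in all 3, where independent lists would give 27.3 and 44.1. In the high temperature library, 94.2% of the 710 had a positive and 96.5% of the 853 a negative log2 fold change, with medians of 1.54 and -2.71, or 1.53 and -2.50 with unread features at their bound. Under low silicate 57.0% and 91.1% had the same sign, with medians of 0.19 and -1.10. These shares lean on the same control libraries and were not tested. In the simulated unchanged groups, as many features with the largest moves common to the 3 comparisons had the same sign in 82.7% and 86.6% under high temperature (medians 1.08 and -0.87) and in 95% and 92.5% under low silicate (medians 1.21 and -0.76). Those simulated features were picked by rank of noise and did not have to be called. Their shares show the pull of shared controls and are not expected values for the 710 and 853. Chosen with one exponential library and measured against the other, the shares were 94.0% or 85.7% and 68.2% or 83.8% under high temperature, and 52.8% or 40.5% and 66.7% or 67.7% under low silicate. The feature comp11834_c0 is a member of the 853, at 464 ± 324 CPM in the exponential phase, and its log2 fold change was -7.10 under low temperature (edgeR adjusted p = 0.00217) and -0.45 under low silicate (edgeR adjusted p = 0.875). The feature comp16328_c0 rose in all 3 and had a log2 fold change of 3.48 under low temperature (edgeR adjusted p = 0.0148).

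**Figure D3:**
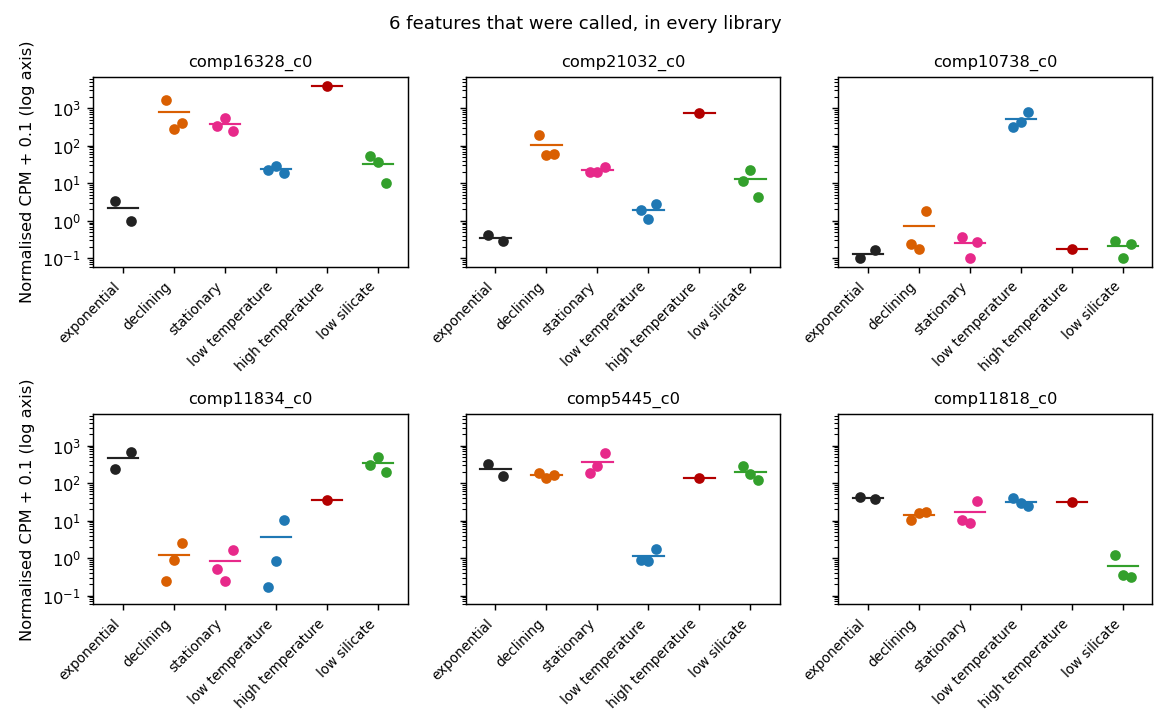
Levels of 6 features of the naming rule in each library, as normalised CPM plus 0.1 on a log axis, by group; points are libraries and lines are group means, and the 6 were picked for display after their values were seen. The feature comp10738_c0 stands at 514 ± 252 CPM under low temperature, comp16328_c0 at 3973 CPM in the high temperature library, and comp11818_c0 at 0.522 ± 0.497 CPM under low silicate.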

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

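Scaling by library totals alone, ranks from low silicate libraries and the 2 settings that leave out doubted features or libraries were chosen after seeing the data. Over 424 recomputations of the named features' log2 fold changes, 376 stayed past the threshold, 48 did not and 0 changed sign. Of the 376, 28 came from the minimum log2 fold change of 1, which keeps the main fit and could not end these calls. Losses came under the fit of 2 groups alone, the replicate block and settings that leave out libraries. The named features were chosen for large, non-overlapping changes in these same data. That choice favoured their staying past the threshold and made a change of sign unlikely from the outset. Simulated 2-fold changes were recovered in 0% to 1.5% of cases at these depths and this spread, and neither depth nor the number of libraries was varied in the simulations.

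Counts of calls for declining, stationary and low temperature against exponential stayed within 1.5 times under RLE scaling, DESeq2, no filter, the fit of 2 groups and a minimum log2 fold change of 1. The stationary count of 4006 became 6405 with library totals alone, 6214 on log2(FPKM + 0.1) and 6351 on log2(FPKM + 1), all of which scale by library totals. Low silicate (75) became 553 with DESeq2, 244 on log2(FPKM + 0.1), 552 on log2(FPKM + 1), 0 with edgeR on the 2 groups alone (2336 had an unadjusted p under 0.05 with all groups) and 41 without exponential 1 and stationary 3. High temperature (931) became 1804 with DESeq2, 1783 on log2(FPKM + 1), 612 with library totals alone and 199 without exponential 1 and stationary 3. Low against high temperature (1927) became 3062 with DESeq2 and 310 on the 2 groups alone. Stationary against declining (22) became 1016 with DESeq2, 56 with RLE scaling, 48 with library totals alone, 223 on log2(FPKM + 0.1), 148 on log2(FPKM + 1), 48 with no filter, 428 on the 2 groups alone, 58 without the features read mostly in exponential 1 and 0 with edgeR without exponential 1 and stationary 3 (2795 had an unadjusted p under 0.05 with all libraries). Apart from the shared scaling, the cause was not tested.

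Leaving out 1 replicate at a time gave 2056 to 2514 calls for declining, 1249 to 3534 for stationary, 2098 to 3683 for low temperature, 6 to 195 for low silicate and 55 to 103 for high temperature, each against exponential. The lowest were without exponential 3, except 6, which was without exponential 1. The range was 0 to 261 for stationary against declining and 1059 to 2278 for low against high temperature. These fits hold fewer libraries, and where 1 exponential library was left it was assumed to vary like the other groups.

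Replicate numbers pair no libraries in the labels. Same-numbered libraries had a mean correlation of deviations from their group means of 0.023 over 26 pairs (-0.239 to 0.447), and -0.01 over 52 pairs with different numbers, and 14 of 52 best matches had the same number. Deviations cancel within a group, so the mean over different numbers largely follows from that over same numbers and is no separate comparison. By pair of groups compared, it was -0.03, -0.05 and -0.03 for declining with stationary, under 0 for exponential with declining, stationary and low temperature, and 0.447 and 0.224 for exponential with low silicate, which share 2 numbers. Declining with low temperature, which were not compared, had 0.29, 0.143 and 0.316. With the replicate block, edgeR called 0 features for stationary against declining, where DESeq2 without it called 1016, and the counts of the other 4 comparisons it could be fitted to stayed within 1.5 times.

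With exponential 1 as the control of the first comparison and exponential 3 of the second, and then the reverse, shared calls in the same direction went from 2499 to 885 and 991 for stationary with declining, 7 to 2 and 3 for low temperature with low silicate, 433 to 47 and 17 for low with high temperature, and 2065 to 716 and 661 for low temperature with stationary. They went from 22 to 6 and 5 for low silicate with stationary and from 24 to 6 and 5 for low silicate with declining. Each list here rests on 1 control library. The stationary to exponential ratio of the share of the most abundant features was 1.19 with 1000 features, where 100 gave 1.36.

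With library totals alone, medians of the 100 most abundant features became 0.79 for stationary and 0.14 for low temperature against exponential, 0.09 for stationary against declining and -0.03 for low against high temperature. Those of the next class, down to rank 1000, became 0.23, -0.11 and 0.06 in the first 3 of these. Medians over all features moved down with them, from -0.10, -0.10, -0.05 and 0.02 to -1.16, -0.71, -0.55 and -0.33. Each class median given here therefore still lay above that of all features. Ranked on the low silicate libraries, the classes no longer passed camera at the preset correlation for low temperature against exponential (medians 0.35 and 0.27) and low against high temperature (0.12 and 0.32).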

Other observations

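The most abundant feature by mean CPM, comp14977_c0, was singled out after its values were seen. It took 0.49% ± 0.20 of the reads in the exponential phase (SD, n = 2), 2.47% ± 0.24 in the declining phase and 2.12% ± 0.85 in the stationary phase (n = 3 each). Its log2 fold change was 2.84 in the declining phase (edgeR adjusted p = 0.024) and 3.08 in the stationary phase (edgeR adjusted p = 0.0175). Under low silicate it took 1.46% ± 0.14 of the reads, with a log2 fold change of 1.55 that did not pass the test (edgeR adjusted p = 0.343). Under low temperature it took 0.71% ± 0.51 (1.21, edgeR adjusted p = 0.246), and 1.08% in the high temperature library.

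The patterns that follow were noticed in these data. The tests of few reads, of scaling, of RNA carried over and of a separate RNA source, in the form given here, were chosen after the results were seen, in place of tests whose bounds were written before. Of the 10 splits of the 6 stationary and declining libraries into 3 and 3, only 1, the real one, gave as many calls: 22, where the highest of the others gave 0. These splits are too few for a share under 0.05.

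A set of 243 features stood at least 8-fold higher in exponential 1 than in each other library, at 1 CPM or more, and held 0.252% of its reads. No other library had more than 11 such features, which argues against few reads per feature as the whole cause, since counting noise would give them in libraries of like depth. Of 274 features chosen without use of exponential 3, 27 (9.9%, 6.6% to 14.0%) reached 25% of the exponential 1 level in exponential 3, which argues against the growth phase as the whole cause, since that needed 50%; the bound written for the opposite case, 10%, lies inside the interval, so the reading rests on the 50% bound, a choice made after the value was seen. RNA of another source may be involved and stays open. The 321 features chosen without low silicate 1 held 0.299% of the reads in exponential 1 and 0.033% in low silicate 1. They held 0.002% in exponential 3 and at most 0.0026% in any other library, all of which entered the choice. Exponential 1 and low silicate 1 also had the highest correlation of deviations from group means, 0.447. A cause shared by these 2 libraries was not tested. Over the 122 of the 321 with at least 50 reads in exponential 1, the SD of the log2 ratio was 1.40. It was 1.17 for features with like counts thinned to the same ratio (mean difference over bootstrap draws 0.21, -0.09 to 0.51). The bound first written, the 1.08 of such features without thinning, left out the counting noise of the low levels in low silicate 1 (median log2 ratio -3.77). Of the 243 features, 56 were called in the declining, 60 in the stationary and 86 in the low temperature comparison, and 0 with edgeR under low silicate.

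Stationary 3 lay apart from stationary 1 and 2 (position 0) on 840 features that separated them from low temperature 1 and 2 (position 1), at a median of 0.35 (quartiles 0.11 and 0.81). Positions 0 and 1 hold by construction, since those libraries chose the features, and a library left out is drawn inward. Low temperature 3, also left out, lay at 0.76, so part of the 0.35 may follow from the choice. How unusual 0.35 is was not tested. The exponential libraries lay as far along, at 0.34 and 0.41, so the axis is not specific to low temperature; on features higher under low temperature stationary 3 lay at 0.57 and they at 0.24 and 0.27, and on those lower at 0.20 and they at 0.56 and 0.70. An exchange of labels with low temperature 3 is argued against, since that library lay at 0.76 (quartiles 0.54 and 0.92). Low temperature RNA carried over in one ratio is argued against as the whole cause: on 11 features nearly absent from stationary 1 and 2, the smallest SD of the log2 ratio of stationary 3 to a low temperature library was 2.51, with 5 features above 50% of the low temperature mean and 1 with no read, against 1.26 between low temperature libraries thinned to that ratio. The mean difference over bootstrap draws was 1.10 (0.10 to 1.98), and 1.01 (0.61 to 1.40) on 48 features chosen with a lower minimum, though the intervals of both SDs taken apart overlap (1.61 to 3.07 and 0.95 to 1.73). A smaller carried share beside other changes, the timing or conditions of that culture, or a batch, were not tested.

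A set of 481 features were called at least 16-fold lower, by fitted log2 fold change, in both the declining and the stationary phase, 341 of them also with unread features at their bound. They held 1.43% ± 0.636 of the reads in the exponential phase (SD, n = 2), 0.616% ± 0.27 under low silicate (n = 3), 0.124% ± 0.027 under low temperature (n = 3), 0.175% in the high temperature library, and 0.023% ± 0.008 and 0.022% ± 0.007 in the declining and stationary phases (n = 3 each). Scaling by abundant features is argued against as the whole cause of such falls, on features chosen by another rule, without a test. It took at least 50 reads in 1 exponential library, at a level by library totals at least 16-fold over the mean of declining 1 and stationary 1. The 654 or 524 features so chosen are not the same set as the 481. In libraries not used to choose them, their median log2 changes by library totals were -4.12 (-4.34 to -3.92) or -5.05 (-5.31 to -4.68), where the scaling factors differed by 1.05. The falls were not confined to the late phases. Under low temperature the 481 had a median log2 fold change of -3.17, and 66.7% were called lower. The median was -4.22 in the high temperature library (-3.53 with bounds) and -1.80 under low silicate, where 1.5% were called lower. These values lean on the same exponential libraries. A separate RNA source in the exponential cultures may contribute and stays open. For this, the 255 of the 481 features with at least 50 reads in exponential 3 were used. The SD of the log2 ratio of low silicate 3 to exponential 3 was 0.97, against 1.06 for like features thinned to the same ratio (mean difference over draws -0.10, -0.27 to 0.08). That of low temperature 2 was 1.54 against 1.73 (mean difference over draws -0.20, -0.40 to 0.01). A response of the diatom to the growth phase or treatment, which the design names, is likewise open.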
